A study of Rattus norvegicus with 36 samples.

How the data were processed

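RNA of brain and of lung was sequenced from 18 six-week-old male Sprague-Dawley rats, per the labels, with 36 libraries in 6 groups per tissue and 3 libraries per group. Sham animals had the cervical artery exposed, and the others had a nylon filament advanced from the right common carotid artery for 2 h and, in the reperfusion groups, withdrawn. RNA was extracted with TRIzol and made into libraries with a stranded mRNA kit. The part of brain or lung taken, the hour of day at sampling, the batch of each library and the rat or rats behind it are not given in the sources used here.

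The deposited tables, 1 per tissue, hold FPKM per gene model, a unit computed by the authors. HISAT2, StringTie 2.1.4 and RSEM, and the genome builds Rnor_6.0 and mRatBN7.2, are named per the submitters' processing notes, without their order or role. Raw reads and counts were not used here. Library columns were matched to samples by the column names that the labels give, and groups and replicate numbers came from the sample titles. Of 34321 named gene models, 27233 matched a RefSeq symbol and 1640 a synonym. There are 41150 gene models for brain and 41259 for lung, of which 152 and 261 are unnamed models that the assembly added. Those unnamed models hold 51.9 to 58.9% of FPKM in brain libraries and 47.8 to 58.3% in lung libraries, and the top 20 models hold 47.4 to 55.2% and 45.9 to 56.7%. FPKM of all other genes depends on that share, and an alternative scaling was therefore run.

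Depth per library is not given in the sources used here. Its relative size was estimated from the commonest log2 ratio between libraries over models listed under 0.15 FPKM in all of them (6034 in brain and 5743 in lung), where a model holds few fragments. A single value per library reproduced 100% of those ratios within 0.03. Pearson r between libraries of a group ran from 0.924 to 0.989 in brain and 0.966 to 0.987 in lung, and 0 pairs of libraries had identical values. The median standard error of a log2 difference was 0.144 in brain and 0.117 in lung.

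Genes with at least 1 FPKM in at least 3 of the 18 libraries of a tissue were kept, and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), 1 fit per tissue over all 18 libraries. A moderated F test covered the 5 differences from sham. Moderated t tests covered each time against sham, 12 h against 2 h and 5 d against 12 h. Adjustment followed Benjamini and Hochberg per comparison, and genes with an adjusted p under 0.05 were called. An exact permutation test of 3 against 3 libraries has a smallest p of 0.1, which is why the moderated tests of limma were used throughout. Brain and lung were fitted apart, and no expression value was tested between the tables.

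Fixed gene lists were tested with camera of limma (preset correlation 0.01, adjusted over all lists and 5 times of a tissue), with camera using a correlation estimated from the data, and with fry. Lists needed at least 3 tested members. Of 205 pairs of list and time in brain 74 passed with the preset correlation, of 215 in lung 85, and with an estimated correlation limma camera passed 0 in both tissues. Genes named in the text are the 10 largest rises and falls per comparison with sham (5 in the others), up to 4 called members per list, and a fixed panel. The rises and falls were taken among called genes with a mean of at least 2 FPKM and a symbol that is not a locus identifier. For these genes all 3 libraries of one group also had to lie above all 3 of the other. Genes named for levels in single libraries, and the thalamic genes, were listed after the values were seen. Overlaps of calls between the tissues were compared with the number that independent lists would share, with a one-sided Fisher exact test. Genes that differ within a group were those with a highest library of at least 5 FPKM and at least 8 times the lowest (offset 0.1 FPKM), classed as a pair where the middle library lay near the highest and as single where it lay near the lowest.

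The whole procedure was tested on simulated data of the same size and spread, with libraries independent of each other. Changes of log2 1 were recovered for 75 to 87% of brain genes and 87 to 93% of lung genes, changes of log2 2 for 94 to 100% and 93 to 100%, and the highest share of false calls was 7.1% and 6.6%. Of 10 lists shifted by log2 0.5, 9 were recovered with the preset correlation. Genes were simulated independently of each other too, so this cannot tell how the list test performs where members of a list go together.

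Groups, tests, filters, lists, the naming rule and a first set of alternatives were fixed before the data were examined. That set was a pseudocount of 0.1, no filter, median-ratio scaling, robust empirical Bayes, the 6 libraries of the groups compared, the replicate number as a block, and the omission of each library in turn. Chosen later were a fit without the 5 d brain libraries or the 1 d lung libraries, the 1 d lung group as its library 2 alone, and a doubling of every standard error, which stands for libraries that each pool RNA of 2 of the 3 rats of a group. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Splicing, transcripts and unnamed models were not analysed here, and genes were not tested for differences between brain and lung. A gene withheld for evaluation is not reported here.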

Results

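Brain and lung of rats were profiled after 2 h of occlusion of the middle cerebral artery, without reperfusion or with 12 h, 1 d, 3 d or 5 d of it, and in sham animals. Each tissue has 18 libraries, 3 per group. The same sham libraries serve every time, and no time has a sham group of its own. Differences from sham therefore hold elapsed time as well as the occlusion, and these cannot be told apart. Values are FPKM, given as mean ± SD (n = 3), and changes are log2 fold changes of FPKM + 1 from limma with p adjusted over all genes. FPKM summed to 902542 to 1152357 per brain library and 932335 to 1117397 per lung library, and 13417 to 14395 and 13998 to 14514 gene models reached 1 FPKM. Read counts are not given in the sources used here. Relative depth, estimated from the smallest values, ran from 0.827 to 1.11 in brain and 0.881 to 1.14 in lung. After filtering, 14952 brain genes and 15174 lung genes were tested.

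Genes of small brain nuclei and of tissues next to the lung differed strongly within groups. Pmch, a neuropeptide gene of the lateral hypothalamus, was listed at 272, 267 and 0.359 FPKM in sham brain libraries 1, 2 and 3. Oxt, the oxytocin gene, had 499, 518 and 0.0811 FPKM in the same libraries, and Tph1, a pineal serotonin-synthesis gene, 0.0942, 70.1 and 69.3 FPKM at 3 d. In lung, Acta1, the skeletal muscle actin gene, had 876, 1.02 and 899 FPKM at 1 d, and Bpifa1, a secreted protein of upper airways, 0.868, 793 and 841 FPKM at 5 d. Counted per gene and group, 166 brain entries had such a spread. Of these, 128 were high at like levels in a pair of libraries and 18 in a single library, and of 232 lung entries 188 and 19. A gene counts again in each group where it had such a spread, as Pmch did in every brain group. Trios of libraries taken across groups put a median of 2.29% (brain) and 6.90% (lung) of such genes in the pair class, against 77.1% and 81.0% within groups. The labels do not state which rats each library holds, and the p-values measure only the spread between libraries. Counts with every standard error doubled are therefore given as an alternative.

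**Figure D1:**
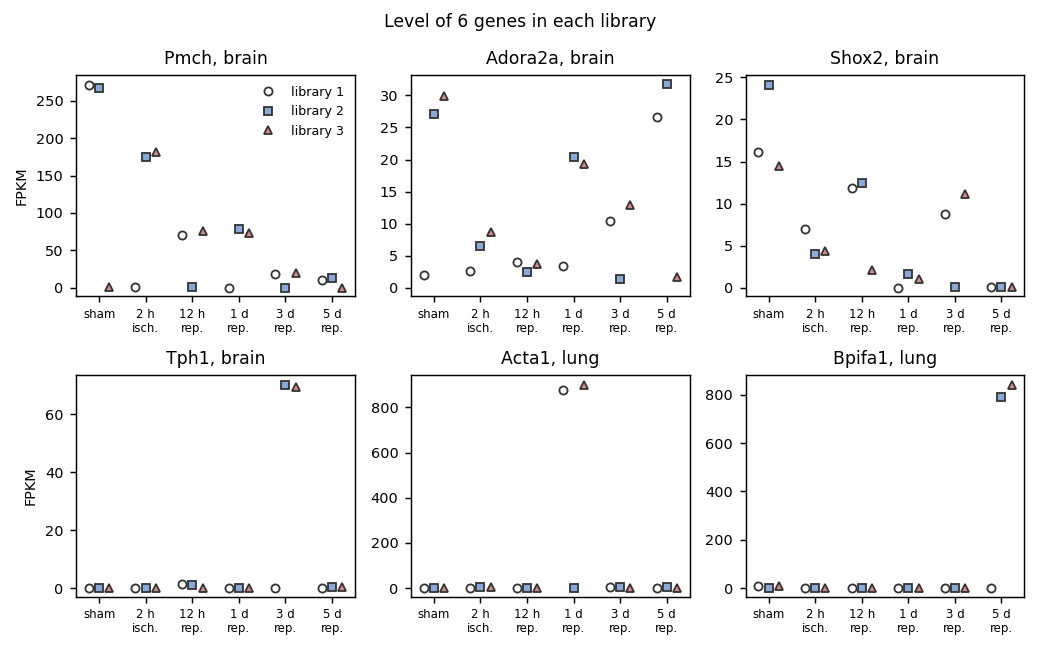
FPKM of Pmch, Adora2a, Shox2 and Tph1 in the 18 brain libraries and of Acta1 and Bpifa1 in the 18 lung libraries, by group (horizontal axis). Within single groups a pair of libraries lies at a like level and the remaining library near 0, as for Acta1 at 1 d in lung (876 and 899 against 1.02 FPKM).

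The test over all groups asks which genes differ anywhere in the course. It called 10565 brain genes and 8124 lung genes. In brain 4699 of them had their highest mean at 5 d and 3376 their lowest. In lung 2378 were highest in sham and 2243 lowest at 2 h of ischaemia. Doubling the standard errors left 880 brain and 48 lung genes.

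**Figure D2:**
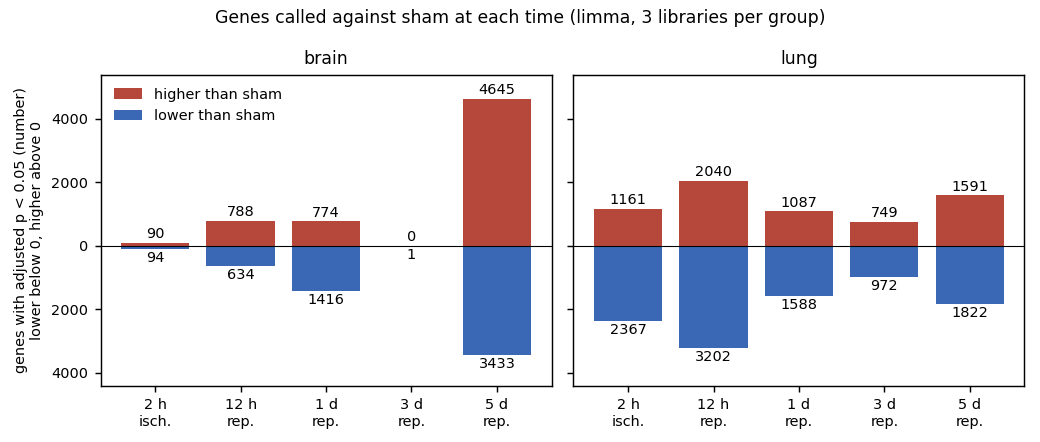
Number of genes called higher and lower than sham (vertical axis) at each time (horizontal axis) in brain and lung. Brain calls number 184 at 2 h, 1 at 3 d and 8078 at 5 d, while lung calls lie between 1721 and 5242 at every time.

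The comparison of 2 h ischaemia with sham in brain asks what changes before blood returns. Gpd1, a glycerol phosphate dehydrogenase induced by corticosteroids in oligodendrocytes, rose from 38.7 ± 4.05 to 195 ± 23.8 FPKM (log2 2.30, adjusted p = 4.60e-04), and Pdk4, which restrains entry of pyruvate into the citrate cycle, from 2.36 ± 0.319 to 13.1 ± 1.30 FPKM. Fkbp5, a chaperone that dampens the glucocorticoid receptor, rose from 10.8 ± 1.67 to 32.6 ± 1.14 FPKM (adjusted p = 0.00234) and Sgk1, a corticosteroid-induced kinase, from 26.4 ± 5.50 to 94.8 ± 7.75 FPKM. Slc2a1, the glucose transporter of the blood-brain barrier, went from 48.1 ± 3.13 to 102 ± 1.92 FPKM (adjusted p = 1.39e-04). The zinc-binding metallothionein transcripts Mt1 (log2 1.89) and Mt2A (log2 1.99) rose, and reads may be divided between these like sequences. Of 14 tested glucocorticoid-responsive genes, 8 rose and 6 did not pass (13 rose when adjusted over the list alone; camera adjusted p = 1.34e-23, and adjusted p = 0.108 with an estimated correlation).

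Tnfrsf11b, the decoy receptor osteoprotegerin, fell at 2 h in brain from 6.25 ± 0.495 to 1.41 ± 0.0164 FPKM (log2 -1.59, adjusted p = 1.69e-06). Slco1a4, an organic anion transporter of brain endothelium, fell from 15.4 ± 0.879 to 6.84 ± 0.782 FPKM, and Ocln, a tight-junction protein, from 4.97 ± 0.456 to 2.15 ± 0.159 FPKM (adjusted p = 0.00334). Of 15 blood-brain barrier genes 4 fell and 11 did not pass (4 fell and 1 rose when adjusted over the list alone; camera adjusted p = 5.45e-04, and adjusted p = 0.549 with an estimated correlation). Of 12 choroid plexus and ependyma genes 1 fell (3 when adjusted over the list alone; camera adjusted p = 1.67e-06, and adjusted p = 0.549 with an estimated correlation). The scores of that list per library were -0.832, 0.453 and 0.379 in sham and -0.881, -2.31 and -0.895 at 2 h, so that sham library 1 lies near 2 h libraries 1 and 3. Fos, an immediate early gene of neuronal activity, had 9.21 ± 1.18 against 19.2 ± 3.70 FPKM and did not pass (adjusted p = 0.347). In all 184 genes were called, 90 higher and 94 lower. Under doubled standard errors limma called 1, Tnfrsf11b (adjusted p = 0.0168), where 1803 genes had an unadjusted p under 0.05 in the fit as estimated.

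After 12 h of reperfusion the comparison with sham asks what changes in brain within the same day. Hspb1, a small heat shock protein, rose from 6.06 ± 1.06 to 128 ± 22.8 FPKM (log2 4.19, adjusted p = 4.63e-04), and Hspa1b, an inducible chaperone whose reads may be divided with its paralog Hspa1a, from 2.75 ± 0.624 to 60.5 ± 28.8 FPKM. Timp1, a protease inhibitor of injured glia, went from 2.35 ± 0.472 to 89.4 ± 32.2 FPKM (log2 4.69, adjusted p = 1.47e-04), Lcn2, a lipocalin of reactive astrocytes, from 1.33 ± 0.180 to 21.4 ± 10.5 FPKM, and Gfap, the astrocyte filament, from 174 ± 15.4 to 566 ± 67.9 FPKM (log2 1.70). Socs3, the feedback inhibitor of cytokine signalling, rose from 0.591 ± 0.0617 to 12.4 ± 6.05 FPKM and Ccl2, a monocyte attractant, from 0.161 ± 0.1 to 10.5 ± 5.21 FPKM (adjusted p = 2.98e-04). Hmox1, which breaks down haem, rose from 3.03 ± 0.346 to 21.0 ± 3.98 FPKM. Necab1, a calcium-binding protein of neurons, fell from 49.1 ± 2.03 to 18.7 ± 1.69 FPKM (log2 -1.35, adjusted p = 0.00135).

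Of 19 tested reactive astrocyte genes 16 rose, as when adjusted over the list alone (median log2 1.36, camera adjusted p = 4.81e-16, and adjusted p = 0.491 with an estimated correlation). Acute phase and STAT3 targets such as Socs3, Lcn2 and Timp1 rose in 12 of 14 (13 when adjusted over the list alone; camera adjusted p = 6.96e-14, and adjusted p = 0.491 with an estimated correlation). Of 15 complement genes, among them C1qb (14.8 ± 0.491 to 51.3 ± 1.19 FPKM), 6 rose (13 when adjusted over the list alone; camera adjusted p = 4.70e-07, and adjusted p = 0.562 with an estimated correlation). Of 18 heat shock proteins 6 rose, as when adjusted over the list alone (camera adjusted p = 8.03e-04, and adjusted p = 0.597 with an estimated correlation). None of 13 striatal neuron genes passed, with a median of -1.12 (camera adjusted p = 0.00315, and adjusted p = 0.817 with an estimated correlation). Striatal scores per library were -1.37, 0.716 and 0.655 in sham and -0.996, -1.74 and -0.901 at 12 h, so that sham library 1 lies below 12 h libraries 1 and 3. Slc6a3, the dopamine transporter of midbrain neurons, was listed at 16.2, 53.7 and 34.3 FPKM in the 12 h libraries against 0.0933 ± 0.0809 FPKM in sham, and Th, the dopamine-synthesis enzyme, at 20.6, 54.9 and 42.0 FPKM. In all 1422 genes were called, 788 higher and 634 lower, and 646 and 761 after median-ratio scaling, which turns the larger direction. With standard errors doubled limma called 0, where 3870 genes had an unadjusted p under 0.05 in the fit as estimated.

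**Figure D3:**
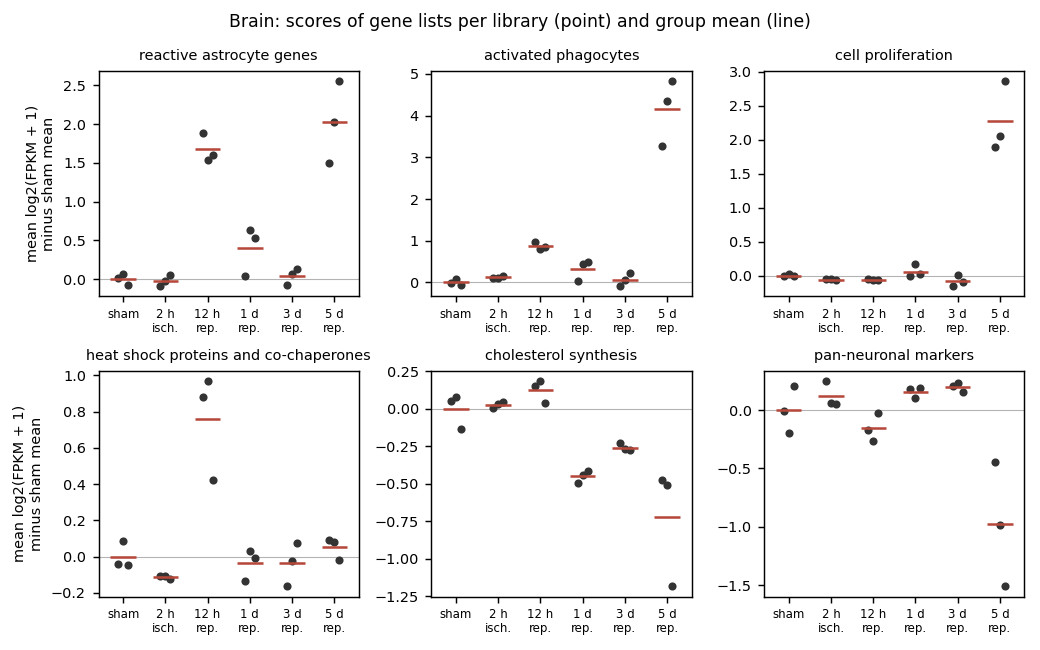
Scores of 6 gene lists in the 18 brain libraries (vertical axis, mean log2 difference from sham; horizontal axis, group). Reactive astrocyte scores reach 1.53 to 1.89 at 12 h and 1.51 to 2.56 at 5 d, and lie between -0.079 and 0.136 at 3 d.

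At 1 d the comparison with sham asks what persists or appears in brain when the 12 h response has had time to settle. Most genes of the oligodendrocyte list fell. Ermn, a cytoskeletal protein of oligodendrocytes, fell from 68.3 ± 8.85 to 21.9 ± 4.31 FPKM (log2 -1.61, adjusted p = 9.77e-04), and Mog, an outer myelin glycoprotein, from 75.5 ± 9.72 to 36.7 ± 3.06 FPKM. Of 14 oligodendrocyte genes 10 fell and 4 did not pass (13 fell when adjusted over the list alone; camera adjusted p = 2.48e-08, and adjusted p = 0.549 with an estimated correlation). Idi1, an early enzyme of the isoprenoid pathway, fell from 11.3 ± 0.277 to 5.22 ± 0.230 FPKM (adjusted p = 0.00233). Of 19 cholesterol synthesis genes, which include Idi1 and Lss, 9 fell (11 when adjusted over the list alone; camera adjusted p = 7.42e-06, and adjusted p = 0.597 with an estimated correlation).

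Genes of other brain regions moved at 1 d too. Of 8 cortical neuron genes 1 rose and 1 fell (4 and 1 when adjusted over the list alone; camera adjusted p = 0.0311 upward, and adjusted p = 0.7 with an estimated correlation), with scores of 0.801, 0.579 and 0.636 at 1 d and 0.017, -0.513 and 0.496 in sham. Of 4 cerebellar neuron genes 2 fell, as when adjusted over the list alone (camera adjusted p = 0.0418, and adjusted p = 0.597 with an estimated correlation), with scores of -1.53, -0.916 and -0.926 at 1 d and 0.027, 0.421 and -0.449 in sham. Tcf7l2, which specifies thalamic neurons, fell from 34.9 ± 9.80 to 3.17 ± 1.49 FPKM (log2 -3.15, adjusted p = 0.00338), Shox2, of the dorsal thalamus, from 18.2 ± 5.19 to 0.896 ± 0.799 FPKM, and Zic1, of the medial thalamus and septum, from 25.4 ± 6.87 to 4.37 ± 0.886 FPKM. Of 11 thalamic genes, listed after the values were seen, 10 fell at 1 d, and the median was -2.28. Ccn3, a matricellular protein of cortical neurons, rose from 34.2 ± 19.0 to 167 ± 13.2 FPKM (log2 2.45, adjusted p = 0.00205), and Lcn2 had 12.6 ± 6.93 FPKM (log2 2.37). Gfap, at 182 ± 74.1 FPKM, did not pass. MHC class II presentation differed in sign, with a median of -0.06, a mean of 0.28 and an upward test that did not pass (camera adjusted p = 0.142), and 3 of 8 genes rose, as when adjusted over the list alone. In all 2190 genes were called, 774 higher and 1416 lower, and 1080 and 1166 after median-ratio scaling. With standard errors doubled limma called 0, where 4438 genes had an unadjusted p under 0.05 in the fit as estimated.

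At 3 d the comparison with sham asks whether the brain response continues, and limma called 1 of 14952 genes, with 2038 at an unadjusted p under 0.05. Mpp6, a membrane scaffold protein of axons and myelinating cells, fell from 14.3 ± 1.12 to 7.87 ± 1.07 FPKM (log2 -0.79, adjusted p = 0.0101). Its call ended in the fit to the 6 libraries of these groups, without sham library 2, without 3 d library 2 and with standard errors doubled, where limma called 0. Gfap had 133 ± 20.0 against 174 ± 15.4 FPKM (adjusted p = 0.617), and Mmp9, a gelatinase of neutrophils and injured vessels, 3.14 ± 1.55 against 0.899 ± 0.683 FPKM (adjusted p = 0.146). No member of the immediate early list passed among 28 (median 0.41, camera adjusted p = 1.03e-06, and adjusted p = 0.549 with an estimated correlation). None of 19 cholesterol synthesis genes passed (median -0.27, 1 fell when adjusted over the list alone; camera adjusted p = 3.29e-05, and adjusted p = 0.597 with an estimated correlation). In simulated data of the same size, with libraries independent of each other, 87% of changes of log2 1 at 3 d in brain were recovered. That simulation cannot tell the share recovered if libraries of a group share RNA. The single call does not show that 3 d equals sham. At 2 h, with 184 calls, fewer genes (1803) had an unadjusted p under 0.05 than at 3 d. The 2 groups were fully separated for 24.2% of genes at 3 d and 25.6% at 2 h. By chance 10% would be, if libraries are independent.

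At 5 d the comparison with sham asks what the brain samples hold late in the course. Phagocyte genes rose. Gpnmb, a lysosomal glycoprotein of lipid-laden phagocytes, rose from 1.93 ± 0.268 to 1138 ± 678 FPKM (log2 8.37, adjusted p = 4.93e-09), Spp1, the secreted protein osteopontin, from 3.51 ± 0.887 to 1261 ± 629 FPKM, and Cd68, a lysosomal marker of macrophages, from 0.504 ± 0.104 to 227 ± 133 FPKM (log2 7.04, adjusted p = 8.36e-09). Trem2, a lipid receptor of microglia, went from 3.95 ± 0.473 to 193 ± 98.7 FPKM and C1qb, a complement starter protein, from 14.8 ± 0.491 to 575 ± 258 FPKM. Cd8a, the co-receptor of cytotoxic T cells, rose from 0.0599 ± 0.0617 to 23.3 ± 12.8 FPKM (log2 4.35). Mmp8, the neutrophil collagenase, had 28.2 ± 16.5 FPKM and was listed at 0 in sham. Mki67, a nuclear protein of dividing cells, rose from 0.292 ± 0.0463 to 5.49 ± 2.24 FPKM (adjusted p = 8.29e-08), and Col3a1, a fibrillar collagen of scars, from 6.31 ± 0.990 to 301 ± 181 FPKM.

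Of the lists, all 19 activated phagocyte genes rose at 5 d in brain, as when adjusted over the list alone (median log2 4.02, camera adjusted p = 3.90e-12, and adjusted p = 0.549 with an estimated correlation). All 25 proliferation genes rose, as when adjusted over the list alone (median 2.18, camera adjusted p = 1.72e-14, and adjusted p = 0.549 with an estimated correlation). So did all 25 extracellular matrix genes, such as Col3a1 and Lum, also when adjusted over the list alone (camera adjusted p = 1.09e-11, and adjusted p = 0.549 with an estimated correlation). All 19 reactive astrocyte genes rose, as when adjusted over the list alone (camera adjusted p = 2.37e-07, and adjusted p = 0.549 with an estimated correlation), with Gfap at 592 ± 214 FPKM (log2 1.69). Heat shock proteins differed in sign, with a median of -0.27, a mean of 0.05 and a downward test (camera adjusted p = 0.118): 4 rose, 10 fell and 4 did not pass, as when adjusted over the list alone.

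Most pan-neuronal genes fell at 5 d in brain. Snap25, a synaptic vesicle fusion protein, fell from 913 ± 120 to 404 ± 139 FPKM (log2 -1.22, adjusted p = 9.63e-05), Nefl, an axonal filament, from 278 ± 19.5 to 121 ± 48.8 FPKM, and Nrn1, an activity-regulated growth protein, from 86.7 ± 18.9 to 22.0 ± 7.96 FPKM. Of 22 pan-neuronal genes 20 fell, as when adjusted over the list alone (median -0.97, camera adjusted p = 5.10e-07, and adjusted p = 0.597 with an estimated correlation), with scores of -0.444, -0.981 and -1.51 in libraries 1, 2 and 3. Library 3 stood apart for other neurons: of 11 inhibitory neuron genes 3 fell and 1 rose, as when adjusted over the list alone (camera adjusted p = 0.114; scores 0.037, -0.147 and -1.32), and none of 13 striatal genes passed, nor when adjusted over the list alone (camera adjusted p = 0.474; scores 0.657, 0.836 and -2.35). Cyp51, a sterol demethylase, fell from 73.7 ± 4.79 to 36.7 ± 12.0 FPKM, and 18 of 19 cholesterol synthesis genes fell, as when adjusted over the list alone (camera adjusted p = 1.00e-06, and adjusted p = 0.597 with an estimated correlation). Of 11 thalamic genes 10 fell (median -2.08). In all 8078 genes were called, 4645 higher and 3433 lower, against 4209 and 4084 after median-ratio scaling, 3396 and 1401 in the fit to 6 libraries, and 1688 and 203 (1891 in all) with standard errors doubled. Among those 1891, 17 of 19 phagocyte, 24 of 25 proliferation and 1 of 22 pan-neuronal genes were counted.

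The comparison of 12 h reperfusion with 2 h ischaemia asks how brain differs between these groups. No group spent the same time without reperfusion, so reperfusion and elapsed time cannot be told apart. Timp1, the protease inhibitor, rose from 2.45 ± 1.00 to 89.4 ± 32.2 FPKM (log2 4.68, adjusted p = 1.89e-04), Hspb1 from 5.77 ± 0.411 to 128 ± 22.8 FPKM and Hspa1b from 2.47 ± 0.213 to 60.5 ± 28.8 FPKM (adjusted p = 3.61e-06). Selplg, the selectin ligand of leukocytes and microglia, fell from 11.1 ± 3.83 to 3.62 ± 0.991 FPKM (adjusted p = 0.00869). In all 993 genes were called, 633 higher and 360 lower. With standard errors doubled limma called 4 (Hspa1b, LOC108348108, Srsf5 and Tnfrsf11b), where 3608 genes had an unadjusted p under 0.05 in the fit as estimated.

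The comparison of 5 d with 12 h asks how the late brain response differs from the early one. Cd68, the macrophage marker, had 227 ± 133 against 1.21 ± 0.295 FPKM (log2 6.49, adjusted p = 2.15e-08) and Gpnmb 1138 ± 678 against 11.1 ± 2.38 FPKM. Mmp12, the macrophage elastase, had 49.3 ± 30.9 FPKM at 5 d and was listed at 0 at 12 h. Hspa1b fell from 60.5 ± 28.8 to 7.02 ± 2.43 FPKM (log2 -2.87, adjusted p = 3.92e-06). Th, the dopamine-synthesis enzyme, fell from 39.2 ± 17.3 to 1.06 ± 0.504 FPKM. Its sham libraries had 6.41, 7.02 and 0.720 FPKM, so 12 h stood above sham. Whether the pieces sampled at 12 h held more midbrain was not tested. In all 7287 genes were called, 4162 higher and 3125 lower, and 1103 with standard errors doubled.

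In lung, the comparison of 2 h ischaemia with sham asks which genes of a distant organ change while the brain artery is closed. Most tested glucocorticoid-responsive and neutrophil genes rose. Fkbp5, the receptor chaperone, rose from 15.8 ± 1.64 to 114 ± 8.86 FPKM (log2 2.78, adjusted p = 1.19e-04), and Tsc22d3, an anti-inflammatory glucocorticoid target, from 96.1 ± 10.9 to 309 ± 22.7 FPKM (log2 1.68, adjusted p = 7.62e-07). Errfi1, a feedback inhibitor of the epidermal growth factor receptor, rose from 26.2 ± 1.73 to 144 ± 22.3 FPKM. Mmp8, the neutrophil collagenase, went from 2.59 ± 0.103 to 28.7 ± 5.25 FPKM, Retnlg, a resistin-like protein of neutrophils, from 3.80 ± 1.27 to 32.8 ± 5.25 FPKM, and S100a9, a calcium-binding alarmin, from 65.6 ± 1.83 to 333 ± 42.2 FPKM (adjusted p = 0.00175). Of 14 glucocorticoid-responsive genes 13 rose (14 when adjusted over the list alone; camera adjusted p = 2.27e-14, and adjusted p = 0.235 with an estimated correlation). Of 17 neutrophil markers 10 rose (13 when adjusted over the list alone; camera adjusted p = 4.65e-09, and adjusted p = 0.324 with an estimated correlation).

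Most tested ciliated cell and B cell genes fell in lung at 2 h. Foxj1, the master regulator of motile cilia, fell from 27.0 ± 3.41 to 11.8 ± 1.23 FPKM (log2 -1.12, adjusted p = 1.82e-04), and all 12 ciliated cell genes fell, as when adjusted over the list alone (camera adjusted p = 3.67e-09, and adjusted p = 0.324 with an estimated correlation). Cyp2f4, a club cell cytochrome, fell from 37.4 ± 10.4 to 7.11 ± 1.82 FPKM. Club and secretory cell scores were 0.573, -1.016 and 0.444 in sham and -1.77, -1.902 and -2.185 at 2 h. Cd79a, part of the B cell receptor, fell from 36.9 ± 7.50 to 17.4 ± 2.43 FPKM (adjusted p = 7.39e-04), with 10 of 14 B and plasma cell genes (12 when adjusted over the list alone; camera adjusted p = 1.74e-05, and adjusted p = 0.362 with an estimated correlation). Myl7, an atrial myosin chain of heart and pulmonary vein sleeves, fell from 28.1 ± 8.70 to 0.0971 ± 0.0822 FPKM (log2 -4.69). Cardiac muscle scores were 0.443, -0.317 and -0.126 in sham and -2.313, -2.315 and -2.363 at 2 h. They lay between -2.672 and -1.39 at 12 h, 1 d and 3 d, and were -1.882, 0.946 and 0.963 at 5 d. Libraries of a group can thus differ in these genes, and whether the sampled pieces differed was not tested. In all 3528 genes were called, 1161 higher and 2367 lower, and 1598 and 1631 after median-ratio scaling. Under doubled standard errors 60 were called, among them Retnlg, Errfi1, Fosl2, Maff and Tsc22d3.

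At 12 h the comparison with sham asks how the lung responds within the same day. S100a8, the partner of S100a9, rose from 25.5 ± 4.80 to 647 ± 129 FPKM (log2 4.61, adjusted p = 8.32e-05), S100a9 from 65.6 ± 1.83 to 1288 ± 71.3 FPKM and Mmp8 from 2.59 ± 0.103 to 56.1 ± 6.00 FPKM. Cxcr2, the chemokine receptor that guides neutrophils, rose from 2.40 ± 0.240 to 28.2 ± 4.43 FPKM (log2 3.09, adjusted p = 7.02e-06). Of 17 neutrophil markers 15 rose (16 when adjusted over the list alone; camera adjusted p = 5.75e-13, and adjusted p = 0.235 with an estimated correlation). Cebpd, a transcription factor of the acute phase, rose from 59.3 ± 16.1 to 198 ± 10.5 FPKM, and Aqp3, a water and glycerol channel, from 1.35 ± 0.428 to 26.0 ± 0.890 FPKM.

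Most tested proliferation, respiratory chain and matrix genes fell in lung at 12 h. Cdk1, the mitotic kinase, fell from 17.0 ± 6.53 to 5.07 ± 0.560 FPKM (log2 -1.50, adjusted p = 1.34e-04), and 23 of 25 proliferation genes fell, as when adjusted over the list alone (camera adjusted p = 1.10e-09, and adjusted p = 0.429 with an estimated correlation). Atp5po, a stalk subunit of ATP synthase, fell from 124 ± 1.81 to 81.1 ± 4.28 FPKM, with 26 of 29 oxidative phosphorylation genes, as when adjusted over the list alone (median -0.41, camera adjusted p = 7.76e-09, and adjusted p = 0.362 with an estimated correlation). Tnc, a matrix glycoprotein of growing alveoli, fell from 32.5 ± 4.29 to 2.17 ± 0.698 FPKM (log2 -3.42, adjusted p = 4.37e-06), and Bgn, a small proteoglycan, from 337 ± 37.9 to 169 ± 4.35 FPKM. Of 25 extracellular matrix genes 15 fell and 3 rose, as when adjusted over the list alone (camera adjusted p = 0.0143, and adjusted p = 0.695 with an estimated correlation). In all 5242 genes were called, 2040 higher and 3202 lower, and 2575 and 2511 after median-ratio scaling. Under doubled standard errors 106 were called, among them S100a9, Mmp8, Cxcr2, Aqp3, Tnc and Cebpd.

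**Figure D4:**
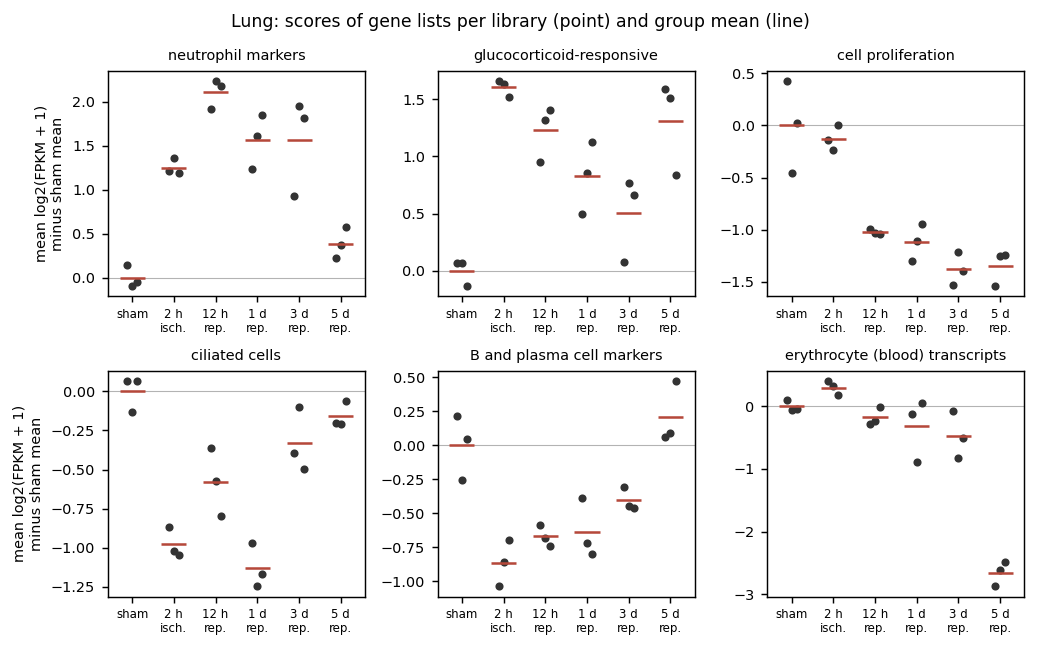
Scores of 6 gene lists in the 18 lung libraries (vertical axis, mean log2 difference from sham; horizontal axis, group). Proliferation scores at 5 d lie between -1.54 and -1.24, and the erythrocyte list falls at 5 d (median log2 -3.46).

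At 1 d the comparison with sham asks whether the lung changes last beyond the day of surgery. S100a9, the neutrophil alarmin, had 657 ± 200 FPKM (log2 3.25, adjusted p = 2.86e-04) and Mmp8 23.3 ± 4.00 FPKM. Of 17 neutrophil markers 14 rose, as when adjusted over the list alone (camera adjusted p = 7.81e-13, and adjusted p = 0.235 with an estimated correlation). Foxj1, the regulator of cilia, fell to 10.2 ± 1.56 FPKM (log2 -1.33, adjusted p = 1.22e-04), Tmem212, a ciliated cell membrane protein, from 7.99 ± 0.373 to 2.09 ± 0.197 FPKM, and Scgb3a2, a secretoglobin of club cells, from 539 ± 56.4 to 139 ± 27.2 FPKM (log2 -1.96). Of 12 ciliated cell genes 11 fell (12 when adjusted over the list alone; camera adjusted p = 1.08e-12, and adjusted p = 0.235 with an estimated correlation). Of 25 proliferation genes 24 fell (25 when adjusted over the list alone; camera adjusted p = 6.85e-17, and adjusted p = 0.347 with an estimated correlation). Mx1, an antiviral GTPase, fell from 17.0 ± 1.69 to 6.10 ± 1.61 FPKM, with 15 of 33 interferon response genes lower and 1 higher (24 and 3 when adjusted over the list alone; camera adjusted p = 5.03e-05, and adjusted p = 0.633 with an estimated correlation).

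Skeletal muscle genes were called higher in lung at 1 d: 3 of 4 tested (4 when adjusted over the list alone; camera adjusted p = 0.00561, and adjusted p = 0.439 with an estimated correlation). Tnni2, a fast-muscle troponin, had 210, 0.635 and 238 FPKM in the 3 libraries, and Krt13, a keratin of squamous epithelium, 274, 0 and 268 FPKM. In all 2675 genes were called, 1087 higher and 1588 lower. Library 2 alone against sham, with its spread taken from the other groups, gave 1256 calls, and with standard errors doubled limma called 0, where 4735 genes had an unadjusted p under 0.05 in the fit as estimated.

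At 3 d the comparison with sham asks what remains in lung while brain calls are few. Neutrophil scores were 0.926, 1.95 and 1.81 in libraries 1, 2 and 3, with S100a8 at 88.0, 865 and 639 FPKM. The list was higher, with S100a9 at 864 ± 559 FPKM (log2 3.37, adjusted p = 7.07e-04) and Cxcr2 at 13.7 ± 4.95 FPKM, and 14 of 17 markers rose, as when adjusted over the list alone (camera adjusted p = 2.00e-14, and adjusted p = 0.235 with an estimated correlation). Inmt, a methyltransferase of lung fibroblasts and vessels, rose from 13.1 ± 2.53 to 123 ± 38.3 FPKM (log2 3.10, adjusted p = 6.44e-04). Ube2c, a mitotic ubiquitin carrier, fell from 11.8 ± 5.52 to 1.17 ± 0.214 FPKM (log2 -2.48, adjusted p = 8.85e-05), and 23 of 25 proliferation genes fell (24 when adjusted over the list alone; camera adjusted p = 6.47e-25, and adjusted p = 0.235 with an estimated correlation). Of 12 ciliated cell genes 2 fell, also when adjusted over the list alone (camera adjusted p = 0.00397, and adjusted p = 0.518 with an estimated correlation). In all 1721 genes were called, 749 higher and 972 lower. With standard errors doubled limma called 0, where 4192 genes had an unadjusted p under 0.05 in the fit as estimated.

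At 5 d the comparison with sham asks what the lung holds at the latest time. Red cell transcripts fell. Hba-a1, an alpha globin whose reads may be divided with Hba-a2 and Hba-a3, fell from 6891 ± 415 to 489 ± 132 FPKM (log2 -3.85, adjusted p = 1.10e-06), Alas2, the haem-synthesis enzyme of red cell precursors, from 31.9 ± 3.18 to 2.03 ± 0.748 FPKM, and Lgals5, a galectin of reticulocytes, from 11.4 ± 0.837 to 1.07 ± 0.410 FPKM. All 11 erythrocyte genes fell, as when adjusted over the list alone (camera adjusted p = 9.10e-14, and adjusted p = 0.235 with an estimated correlation). Pf4, a platelet chemokine, had 61.8, 27.6 and 43.2 FPKM at 5 d against 51.1, 40.8 and 45.3 FPKM in sham.

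Immediate early genes rose in lung at 5 d. Egr1, a transcription factor of early growth responses, rose from 7.53 ± 1.47 to 47.7 ± 17.6 FPKM (log2 2.46, adjusted p = 1.03e-04), and Zfp36, which destabilises cytokine messages, from 58.7 ± 10.1 to 169 ± 21.2 FPKM. Of 24 immediate early genes 21 rose, as when adjusted over the list alone (camera adjusted p = 6.48e-17, and adjusted p = 0.235 with an estimated correlation). Tsc22d3, the glucocorticoid target, was again higher (253 ± 29.2 FPKM), with 11 of 14 genes of its list (12 when adjusted over the list alone; camera adjusted p = 4.65e-09, and adjusted p = 0.324 with an estimated correlation). Cdk1 fell to 2.97 ± 0.367 FPKM, with 22 of 25 proliferation genes (23 when adjusted over the list alone; camera adjusted p = 1.88e-17, and adjusted p = 0.347 with an estimated correlation). Rsad2, the antiviral enzyme viperin, fell from 6.55 ± 0.365 to 1.93 ± 0.497 FPKM, with 23 of 33 interferon response genes lower and 2 higher (27 and 2 when adjusted over the list alone; camera adjusted p = 5.58e-08, and adjusted p = 0.471 with an estimated correlation). Ifit1, another antiviral gene, rose from 0.281 ± 0.153 to 6.86 ± 3.69 FPKM (log2 2.49). Col3a1, the fibrillar collagen, fell from 668 ± 67.3 to 195 ± 102 FPKM, with 18 of 25 matrix genes (19 lower and 1 higher when adjusted over the list alone; camera adjusted p = 2.06e-06, and adjusted p = 0.429 with an estimated correlation). Scores in 5 d libraries 1, 2 and 3 were -0.922, -0.322 and -0.575 for matrix genes and -0.921, -0.407 and -0.262 for interferon genes. Library 1 also stood apart for club and secretory cell genes (-1.211, 1.222 and 1.279). In all 3413 genes were called, 1591 higher and 1822 lower. Under doubled standard errors 20 were called, among them Hba-a1, Alas2, Lgals5, Zfp36, Fosl2 and Tsc22d3.

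The comparison of 12 h reperfusion with 2 h ischaemia asks how lung differs between these groups. Here too reperfusion and elapsed time cannot be told apart, as no group spent the same time without reperfusion. Inmt, the methyltransferase, rose from 15.8 ± 6.82 to 101 ± 27.4 FPKM (log2 2.66, adjusted p = 2.27e-04), and Angptl4, an inhibitor of lipoprotein lipase, from 4.84 ± 2.05 to 28.5 ± 2.36 FPKM. Mfap4, an elastic fibre protein, fell from 2592 ± 86.6 to 425 ± 68.9 FPKM (log2 -2.62, adjusted p = 1.17e-04), and Tnc, the matrix glycoprotein, from 25.3 ± 3.47 to 2.17 ± 0.698 FPKM. In all 4463 genes were called, 2390 higher and 2073 lower, and 69 with standard errors doubled.

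The comparison of 5 d with 12 h asks how the late lung differs from the early one. Mmp8, the neutrophil collagenase, fell from 56.1 ± 6.00 to 2.87 ± 0.726 FPKM (log2 -3.89, adjusted p = 3.00e-05), S100a8 from 647 ± 129 to 45.2 ± 17.8 FPKM and Hba-a1 from 6179 ± 1380 to 489 ± 132 FPKM (adjusted p = 2.12e-06). Myl7, the atrial myosin chain, had 24.1 ± 18.0 against 0.198 ± 0.182 FPKM (log2 3.90), with 3.51, 32.0 and 36.8 FPKM in 5 d libraries 1, 2 and 3. In all 2900 genes were called, 1746 higher and 1154 lower, 1283 and 1500 after median-ratio scaling, and 8 with standard errors doubled.

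The overlap of brain and lung calls asks which genes move the same way in both tissues at a time. Of 12714 genes tested in both, 36 were higher in both at 2 h, against 6.3 for independent lists (Fisher exact p = 3.08e-19). They include Fkbp5 (log2 1.52 in brain, 2.78 in lung), Mt2A (1.99 and 3.77), Nfkbia, an inhibitor of NF-kB (1.26 and 1.52), and Ddit4, a stress inhibitor of growth signalling (0.83 and 1.49). Lower in both at 2 h were 22 genes (11.3 for independent lists, Fisher exact p = 0.00113). At 12 h 199 were higher in both (97.5 for independent lists, Fisher exact p = 5.27e-25), among them Socs3 (2.96 and 1.72), Lrg1, an acute phase glycoprotein (2.73 and 2.19), and Cebpd (1.87 and 1.76). Lower in both were 107 genes at 12 h (118.6 for independent lists, Fisher exact p = 0.902), among them Dbp, a clock output gene (-0.87 and -2.52). At 1 d 86 were higher in both (42.4 for independent lists, Fisher exact p = 1.53e-10) and 140 lower (119.7, Fisher exact p = 0.0240, and 0.177 after median-ratio scaling or 0.0944 with a pseudocount of 0.1). At 5 d 548 were higher in both (473.4 for independent lists, Fisher exact p = 4.64e-06) and 291 lower (311.7, Fisher exact p = 0.925, but 9 against 2.8 with Fisher exact p = 0.00217 for log2 fold changes of at least 1 in size). Opposite directions at 5 d, tested after the counts were seen, held for 754 genes higher in brain and lower in lung (556.5 for independent lists, Fisher exact p = 6.54e-28) and 257 lower in brain and higher in lung (265.1, Fisher exact p = 0.733, but 5 against 1.8 with Fisher exact p = 0.0363 for log2 fold changes of at least 1 in size). At 3 d 0 genes were shared, since limma called 1 gene in brain. Both tissues came from 18 rats, so independent lists describe the overlap and are not its value without an effect. With standard errors doubled limma called 1, 0 and 0 brain genes at 2 h, 12 h and 1 d (1803, 3870 and 4438 at an unadjusted p under 0.05 in the fit as estimated). The overlaps at those times rest on the errors as estimated.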

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

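The tests of the 3 patterns weighed here were chosen after the results were seen, and the counts over other splits of the libraries were planned. For the comparisons of 3 with 3 libraries, 10 splits exist, too few for a share under 0.05. In brain the real split and the highest other gave 184 and 1 calls at 2 h, 1422 and 3 at 12 h, 2190 and 1 at 1 d, 1 and 1 at 3 d (3 of the 10 splits gave as many), 8078 and 1 at 5 d, 993 and 1 for 12 h against 2 h, and 7287 and 1 for 5 d against 12 h. In lung they gave 3528 and 0 at 2 h, 5242 and 1 at 12 h, 2675 and 0 at 1 d, 1721 and 2 at 3 d, 3413 and 0 at 5 d, 4463 and 0 for 12 h against 2 h, and 2900 and 1 for 5 d against 12 h. Each of these counts is from limma. Of 100 groupings of the 18 libraries, 1, the real one, gave as many genes in the F test in brain (10565 against 6578 at most in the others) and in lung (8124 against 1520). That argues against chance if the libraries are independent of each other, though 100 groupings cannot exclude it. With RNA shared within groups, which the next paragraph leaves open, the real grouping would come out on top without any effect of the occlusion. The count then says nothing against chance. For the lists, 57 of 100 groupings gave at least the 74 pairs of list and time passed in brain (highest 129), so chance is not excluded. In lung 4 of 100 gave at least the 85 passed (highest 98). That share, under 0.05, argues weakly against chance if the libraries are independent of each other. Camera with an estimated correlation passed 0 of 215 pairs in lung.

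The pattern with the widest reach is that genes such as Pmch and Oxt in sham brain or Acta1 in lung at 1 d are near 0 in 1 library of a group and high at a like level in the other pair. A fixed pair of libraries made from the same RNA in each group is argued against, as in 7 groups each of 2 libraries was near 0 for 3 or more genes. Sets of rare genes high in a pair numbered 7 and sets high in a single library 1, where genes were picked by their spread and not by shape. The single set included Ckm (9.17), Tnni2 (10.4) and Tnnt3 (11.3 FPKM) in brain library 3 at 5 d. Not every set high in a pair marks another tissue, as brain genes low in library 1 at 5 d include the macrophage markers Cd163 and Msr1. Independent entry of pieces of other tissue into single libraries is thus argued against for the largest sets, of 97 genes in lung at 1 d and 25 in brain at 3 d. For the smaller sets it is not decided. Also open is that libraries of a group share RNA of the same rats, as 12 of 12 groups had more genes high in a pair than in a single library.

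The few calls in brain at 3 d, where limma called 1 gene (Mpp6, with 2038 at an unadjusted p under 0.05), were weighed next. A fit without the 5 d libraries raised the calls from 1 to 67 at 3 d, from 184 to 533 at 2 h and from 1422 to 3201 at 12 h. The spread of the 5 d libraries thus kept some genes from being called at 3 d. As the only reason it is argued against, as 3 d stayed well below the other times in that fit. An exchange of sham and 3 d labels cannot be told apart from the given labels: reactive astrocyte scores reached 0.063 in sham at most and 1.533 at least at 12 h, but were as low as 0.047 at 1 d, so a late library can score like sham. Whether the 3 d samples held tissue outside the lesion or tissue whose response had passed cannot be told apart from these tables, as the part of brain sampled is not given and the 3 d scores (-0.079 to 0.136) overlap those of sham.

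Thalamic genes such as Tcf7l2 and Shox2 were lower than sham in median at every time (-1.65 at 2 h, -0.65 at 12 h, -2.28 at 1 d, -1.15 at 3 d, -2.08 at 5 d), with 1, 2, 10, 0 and 10 of 11 called by limma. General loss of neurons is argued against for 2 h and 1 d, where the pan-neuronal median was 0.09 and 0.10, and not for 5 d, where it was -0.97. A varying share of thalamus in the sampled piece stays open. Deviations of these genes from their group means went together (mean correlation 0.656, against a 95th percentile of 0.108 in 1000 random sets). That value cannot decide it, as the genes were listed after the values were seen and the random sets were matched on expression alone. Lower expression within thalamic neurons cannot be told apart from a varying share of thalamus, since the part sampled is not given. For 6 of 11 genes the highest 12 h library reached the lowest sham library.

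The remaining results differ in direction between brain and lung, and the difference was not tested. Extracellular matrix scores at 12 h averaged 1.14 in brain (0.866 to 1.32) and -0.497 in lung (-0.513 to -0.467). Oxidative phosphorylation at 12 h stood at 0.127 (0.039 to 0.266) and -0.409 (-0.530 to -0.331), a difference not tested. Interferon response genes at 5 d had 0.831 (0.632 to 1.18) and -0.530 (-0.921 to -0.262), likewise not tested. Proliferation at 5 d had 2.27 (1.89 to 2.86) and -1.35 (-1.54 to -1.24), not tested. Matrix genes at 5 d reached 3.09 (2.14 to 3.73) and -0.606 (-0.922 to -0.322), not tested.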

How the results depend on the processing

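Planned were the pseudocount, filter, scaling, robust, block, 6-library and leave-one-out fits and the other list tests, while the doubled standard errors, the fits without the 5 d or 1 d libraries and the fit to 1 d library 2 were chosen after the results were seen. No call of a named gene turned direction in the first group of fits. For genes named as the largest rises and falls this was fixed in advance except under scaling, as their libraries did not overlap between the groups. Calls of named genes that ended numbered 490 of 2574 in brain and 689 of 4368 in lung over all single omissions, 11 of 429 and 29 of 728 with scaling, 59 and 85 with no filter, 47 and 110 with 6 libraries, 8 and 12 with a pseudocount of 0.1, 18 and 16 with the replicate block, and 2 and 9 with robust empirical Bayes. Where a value moved, the cause was not tested, except that doubling raises every p by construction.

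With standard errors doubled limma called in brain 880 genes in the F test, 1 at 2 h (Tnfrsf11b, of 1803 at an unadjusted p under 0.05 in the fit as estimated), 0 at 12 h (3870), 0 at 1 d (4438), 0 at 3 d (2038), 1891 at 5 d, 4 for 12 h against 2 h (Hspa1b, LOC108348108, Srsf5 and Tnfrsf11b, of 3608) and 1103 for 5 d against 12 h. In lung it called 48 in the F test, 60 at 2 h, 106 at 12 h, 0 at 1 d (4735), 0 at 3 d (4192), 20 at 5 d, 69 for 12 h against 2 h and 8 for 5 d against 12 h. Without the 5 d libraries brain calls were 533 at 2 h, 3201 at 12 h, 3793 at 1 d, 67 at 3 d and 2742 for 12 h against 2 h. In lung library 2 alone as the 1 d group, its spread taken from other groups, gave 1256 calls. With only the 6 libraries compared, brain had 2 calls at 3 d, not Mpp6, and 4797 at 5 d, 1579 for 12 h against 2 h and 3461 for 5 d against 12 h, and lung had 1458 at 5 d and 860 for 5 d against 12 h. At 3 d in brain limma gave 12 calls with a pseudocount of 0.1, 4 with no filter and 2 with scaling, Mpp6 among each.

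Median-ratio scaling moved the split of higher and lower calls in brain at 12 h from 788 and 634 to 646 and 761, at 1 d from 774 and 1416 to 1080 and 1166 and at 5 d from 4645 and 3433 to 4209 and 4084, and in lung from 1161 and 2367 to 1598 and 1631 at 2 h, from 2040 and 3202 to 2575 and 2511 at 12 h and from 1746 and 1154 to 1283 and 1500 for 5 d against 12 h. Lists passed by camera with an estimated correlation numbered 0 in brain (74 with the preset one, 56 by fry) and 0 in lung (85, 91 by fry). The 1429 shared brain and lung calls became 88 at a log2 fold change of at least 1 in size.

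Leaving out 1 library at a time, brain calls ran from 9747 to 11133 in the F test and 6371 to 9013 at 5 d, 5684 to 8389 for 5 d against 12 h, and lists from 70 to 80. Lung calls ran from 7047 to 8364 in the F test, 2565 to 2823 at 2 h, 3839 to 4476 at 12 h, 3218 to 3970 for 12 h against 2 h, and lists from 76 to 93. At 2 h in brain (70 to 139) they were 70 without sham 2, 107 without sham 3, and 94, 71 and 82 without 2 h libraries 1, 2 and 3. At 12 h in brain (499 to 1031) they were 896, 911 and 499 without sham 1, 2 and 3, and 802 and 614 without 12 h libraries 1 and 2. At 1 d in brain (803 to 1826) they were 1358 and 803 without sham 1 and 2, and 1026 and 1216 without 1 d libraries 1 and 2. At 3 d in brain (limma, 0 to 96) they were 10, 0 and 96 without sham 1, 2 and 3, and 63 and 0 without 3 d libraries 1 and 2, and Mpp6 was lost at the 0 counts. For 12 h against 2 h in brain (305 to 999) they were 367, 305 and 427 without 2 h libraries 1, 2 and 3, and 315 and 342 without 12 h libraries 1 and 2. In lung they were 1653 and 1620 without sham 1 and 3 at 1 d (1620 to 2231), 932 and 861 without sham 1 and 3 and 743 without 3 d library 3 at 3 d (743 to 1428), 2241 without 5 d library 1 at 5 d (2241 to 4014), and 1895 and 1681 without 12 h libraries 1 and 2 for 5 d against 12 h (1681 to 2744).

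Replicate numbers did not pair the libraries: over 45 pairs with the same number the mean correlation of deviations was -0.016 in brain and 0.002 in lung, and 7 and 8 of 18 libraries went best with their own number. With the number as a replicate block brain calls were 10151 in the F test, 161 at 2 h, 1338 at 12 h, 2009 at 1 d, 1 at 3 d (limma, Mpp6), 7956 at 5 d, 915 for 12 h against 2 h and 7119 for 5 d against 12 h, with 74 lists. The replicate block in lung gave 7809 in the F test, 3430, 5132, 2515, 1560 and 3317 against sham in order of time, 4382 for 12 h against 2 h and 2786 for 5 d against 12 h, with 86 lists.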

Other observations

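Fits with doubled standard errors and the reading of clock genes were chosen after the results were seen, and the list and gene tests named here were planned. Clock genes moved in lung. Dbp, a clock output factor, fell from 67.6 ± 5.93 to 12.0 ± 5.66 FPKM at 12 h (limma log2 -2.52, adjusted p = 3.51e-05) and stood at 17.3 ± 3.94 FPKM at 1 d and 19.0 ± 2.02 FPKM at 5 d. Nr1d1, a repressor in the clock loop, fell from 94.1 ± 4.95 to 13.2 ± 7.44 FPKM at 12 h, while Arntl, the clock activator, rose from 4.46 ± 0.183 to 18.9 ± 1.53 FPKM (adjusted p = 1.95e-05). In brain at 5 d Nr1d1 fell from 47.1 ± 7.43 to 23.0 ± 5.81 FPKM. Of 17 clock genes in lung at 12 h 7 rose and 6 fell, as when adjusted over the list alone, with a median of 0.03, a mean of -0.08 and no pass by camera (adjusted p = 0.494).

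Trophic genes parted in brain at 5 d. Igf1, a growth factor of microglia and macrophages, rose from 1.5 ± 0.102 to 23.9 ± 11.7 FPKM (limma log2 3.19, adjusted p = 5.34e-07), while Bdnf, a neuronal growth factor, fell from 4.41 ± 1.64 to 0.878 ± 0.467 FPKM (log2 -1.51). Of 11 trophic and regeneration genes 3 rose and 4 fell, as when adjusted over the list alone (median -0.02, mean 0.19, downward camera test, adjusted p = 0.742). Of 5 T and NK cell genes, with Cd8a, 4 rose, as when adjusted over the list alone (camera adjusted p = 0.00315, and adjusted p = 0.549 with an estimated correlation). In lung Esm1, a proteoglycan of activated endothelium, rose from 8.77 ± 0.938 to 64.6 ± 20.7 FPKM at 5 d (log2 2.71), and Ccl2, which rose in brain at 5 d, fell from 3.67 ± 0.945 to 1.22 ± 0.425 FPKM.

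A hypothesis for the first hours is that stress hormones reach both organs, since Fkbp5, Sgk1 and Tsc22d3 are glucocorticoid targets and rose at 2 h in brain or lung. Hormone levels, or adrenalectomised animals, would test it and were not analysed here. Scores of the glucocorticoid-responsive list were not high at 2 h alone. In brain they were 1.166 to 1.379 at 2 h, 0.803 to 1.378 at 12 h, 0.445 to 0.657 at 1 d, 0.176 to 0.213 at 3 d and 0.661 to 1.3 at 5 d. In lung they were 1.525 to 1.662 at 2 h, 0.954 to 1.407 at 12 h, 0.495 to 1.127 at 1 d, 0.074 to 0.77 at 3 d and 0.841 to 1.59 at 5 d. Anaesthesia and the hour of sampling, which the labels do not tie to groups, may move the same genes and the clock genes. In limma with standard errors doubled, 60 calls were kept in lung at 2 h, Tsc22d3 among them, and 1 in brain (Tnfrsf11b, of 1803 at an unadjusted p under 0.05 in the fit as estimated).

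For 5 d a hypothesis is that phagocytes and dividing cells fill the lesion in brain while red cell transcripts leave the lung and neutrophil transcripts drop from their 12 h level. Neutrophil scores in lung at 5 d (0.218, 0.369 and 0.571) still lay above those of sham (-0.094 to 0.142). Cell counts in sections of the sampled parts would test this hypothesis and were not made here. Under doubled standard errors 1891 brain calls and 20 lung calls were kept, with 17 of 19 phagocyte genes in brain and 5 of 11 erythrocyte genes in lung. Loss of red cells through blood drained at sampling could give the lower globins too, and Pf4 of platelets (61.8, 27.6 and 43.2 FPKM at 5 d against 51.1, 40.8 and 45.3 in sham) did not show a like fall. Erythrocyte scores at 5 d were -2.872, -2.608 and -2.487 in lung. In brain they were -0.024, -0.329 and -0.074 (sham -0.134 to 0.19), so a fall of that size was seen in lung and not in brain. No test here separates these explanations.

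Cells were not counted, and a lower transcript of a cell type is open to fewer cells, a different piece of tissue or lower expression. The libraries that would settle the rats behind each column, reads with variants of outbred animals, were not analysed here. Measurements of spatial origin, such as sections of the sampled part, would settle the thalamic genes (mean correlation 0.656 within groups) and the midbrain genes, for which no such correlation was computed.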
